A study of Streptomyces clavuligerus with 4 samples.

How the data were processed

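Total RNA from 4 Streptomyces clavuligerus strains was sequenced after removal of rRNA, on a DNA nanoball platform, per the labels' protocols. The strains were the wild type, a strain with adpA deleted, a strain carrying adpA on the plasmid pSPG under a glycerol-inducible promoter, and a strain carrying the empty plasmid. Each culture was 100 ml of TYD medium, grown for 48 h at 28 °C and 220 rpm, and 2 ml was taken for RNA. Each strain had 1 library, labelled a pooled sample; how many cultures entered a pool was not given in the sources used here. Whether glycerol was added, and whether the libraries kept strand, was also not given there.

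Each library had its own deposited table with an identifier, a length, an expected count and an FPKM value per feature. Expected counts are read counts estimated per gene, not scaled between libraries, per the file headers and the values, of which 98.6% to 98.9% per library were whole. The FPKM values, computed by the authors, are fragment counts scaled to gene length and library total, per the file headers. The submitters' processing notes name Bowtie, Bowtie2 and RSEM, with no versions or roles. The genome build and annotation were not given in the sources used here. A feature with a value above 0 in one table and no entry in another was given 0 counts there. The tables together held 6982 features, 6934 of them SCN_RS locus tags and 48 numbered BGI_novel features, and 3889 were listed in all 4 tables.

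The tables do not pair identifiers with gene names. The reference gene table of the assembly ASM551946v1 held 7015 genes, and 0 identifiers of the deposited tables matched any of its identifiers, tags, names or synonyms. Locus tags are therefore given as deposited, no gene is named, and adpA, the 24 gene lists fixed beforehand and the replicons were not looked up. Because genes could not be named, at most 2 tags that were higher and 2 that were lower are printed for each comparison, and groups of genes are described as stretches of adjacent tags. Reads shared between near-identical genes could have been split by the authors' counting, and tags of this kind were not set apart here.

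Expected counts were rounded to whole numbers before use. Library sizes were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, computed over all 4 libraries. Log2 ratios were differences of log2 CPM, counts scaled to a fixed library total, with a prior count of 2, computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes with at least 10 counts in at least 1 of the 2 libraries compared were used, and a gene was called higher or lower at 2-fold or more. With 1 library per strain no difference had a replicate check, so no p-value was computed and the 2-fold rule is a rule of size. Intervals of 95% are exact Poisson for counts, and Clopper-Pearson for shares and for ratios of 2 counts. They cover counting error only, since PCR copies are not independent molecules. Where a count was 0, shares and folds were computed against a floor of 3 counts per library, the one-sided 95% limit of a count of 0, and these folds are lower bounds.

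The comparisons were deletion with wild type, overexpression with vector control, and vector control with wild type. Genes past 2-fold in the same direction against both the wild type and the vector control were counted for the deletion and for the overexpression strain. Pairs of directions between comparisons were set beside the overlap of independent lists, which is the product of both counts over the genes used in both. For comparisons that share a library, 100 sets of 4 unchanged libraries were simulated with Poisson counts. The rule for named genes took those with at least 50 counts in 1 of the 2 libraries, ranked by log2 ratio with the prior count, which shrinks ratios of low counts, so folds of the printed counts can fall in another order. It asked for 2-fold in the same direction against both references and took 10 per direction for the deletion and for the overexpression strain, 5 per direction for the vector control against wild type, and 5 per orientation for genes that moved oppositely. The condition that a gene have a product name was dropped, as the rule provided. These choices and the alternatives of scaling, filter, prior count, unit and reference were set before the data were examined.

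After the data were examined, runs of locus tags without counts were defined in the order of the tag numbers. At least 12 consecutive tags at 0 started a run, runs up to 20 tags apart were joined, and a joined run of at least 50 tags was kept if at least 60% of its tags had a count in the vector control and its share of counts was under 10% of the vector control's. These limits were set with the runs and blocks in view, and the 10% was raised from 1% so that run 4 was kept. The part of run 1 nearly without counts in both plasmid strains is its longest stretch of tags with at most 3 counts in each, also picked out then. In the deletion 2 further blocks missed these limits, and they and the tags between runs 2 and 3 count as outside the runs unless stated. Stretches of at least 5 adjacent tags outside these runs that all passed 2-fold in the same direction were also defined then, and set beside 1000 shuffles of the tag order. The order of tag numbers was taken as gene order; it can break where the assembly behind it breaks.

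The total of rounded counts was 464775 in the wild type, 770260 in the deletion, 821594 in the overexpression strain and 936697 in the vector control. A count of 0 with the floor of 3 counts allowed up to 6.33 TMM-scaled CPM in the wild type and 3.67 in the deletion. TMM factors ran from 0.916 in the overexpression strain to 1.06 in the deletion. The calculation was tested on simulated counts with 200 changed genes per comparison. Changed genes were drawn from those with a mean expected count of at least 50 in the libraries compared, and the counts held Poisson noise only. Recovery of genes with fewer counts, and calls under differences between cultures, were therefore not tested. For deletion with wild type it recovered 50 of 50 genes at 4-fold higher and 49 of 50 at 3-fold lower, and it called 125 of 3983 unchanged genes. For overexpression with vector control it recovered 47 of 50 genes at 3-fold lower and called 96 of 4342 unchanged genes, and for vector control with wild type 48 of 50 and 129 of 4184. Alternatives used DESeq2 1.42.0 size factors, library totals, other filters and prior counts, FPKM as log2(value + 1) and the other reference strain. Figures were drawn with matplotlib 3.10.9.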

Results

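RNA-seq was used to ask how the transcriptome of Streptomyces clavuligerus, a soil actinomycete that makes clavulanic acid and cephamycin C, differs when adpA is removed or supplied on a plasmid. AdpA is a transcriptional regulator of the AraC family that controls development and secondary metabolism in other Streptomyces. The 4 libraries were 1 each from the wild type, the adpA deletion, the adpA overexpression strain and its vector control, all at 48 h. Rounded totals ranged from 464775 counts in the wild type to 936697 in the vector control, and the median count of a listed feature ranged from 13 in the wild type to 26 in the deletion. A single feature of 396 bp held 22.5% of all counts in the wild type, 15.5% in the deletion, 9.06% in the overexpression strain and 5.33% in the vector control. Because each strain had 1 library, no difference described here has a replicate check, and a ratio between strains is also a ratio between single cultures or pools. The tables do not pair tags with gene names, so the level of adpA was not looked up and the strain labels were not checked against it.

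The deletion library had almost no counts over 3 long runs of consecutive locus tags. Run 1, from SCN_RS00020 to SCN_RS00385, held 66 tags and had 0 counts in the deletion, which allows a share of up to 0.000389%. The same tags had 3870 counts in the wild type, 0.833% of that library (Clopper-Pearson 0.807% to 0.859%), 937 in the overexpression strain and 1141 in the vector control, so their share was at least 2138-fold lower in the deletion than in the wild type. A single tag held 1829 of the 3870 counts, and without it the share was at least 1127-fold lower. Within run 1 the 21 tags SCN_RS00180 to SCN_RS00285 were also nearly without counts in both plasmid strains, with 1350 counts in the wild type, 14 in the overexpression strain and 8 in the vector control. Run 2, from SCN_RS25825 to SCN_RS28295, held 422 tags with 63 counts in the deletion (Poisson 48.4 to 80.6) and 23847 in the wild type, a share 627-fold lower (490 to 817). Run 3, from SCN_RS28570 to SCN_RS38500, held 1410 tags with 4 counts in the deletion (1.09 to 10.2), against 29282 in the wild type, 54405 in the overexpression strain and 62639 in the vector control.

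Together runs 1 to 3 covered 1898 tags and took 12.3% of the counts in the wild type, 10.3% in the overexpression strain, 9.46% in the vector control and 0.0087% in the deletion (0.00674% to 0.011%). Only 10 of these tags had any count in the deletion, and 2 of them held 34 and 20 of the 67 counts. Of 66 tags with at least 50 counts in each of the other 3 libraries, 65 had 0 counts in the deletion. Tags at 0 in the deletion defined the runs, so these low counts are part of the definition. The 42 tags between runs 2 and 3 had 14 counts in the deletion and 1199 in the wild type, a share 142-fold lower (84.3 to 260). Later in the tag order 2 further blocks were mostly without counts in the deletion but missed the limits set for a run. SCN_RS39520 to SCN_RS40555, 98 tags, had 309 counts on 6 tags in the deletion and 1035 counts on 56 tags in the wild type. SCN_RS41795 to SCN_RS43040, 61 tags, had 0 counts in the deletion, 192 in the wild type, 172 in the overexpression strain and 349 in the vector control.

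Part of run 3 was also nearly without counts in the wild type and in the overexpression strain. Run 4, from SCN_RS28725 to SCN_RS31070, held 234 tags, of which 232 had a count in the vector control, 41 in the wild type, 5 in the overexpression strain and 1 in the deletion. It held 6302 counts in the vector control, 0.673% of the library (0.656% to 0.69%), 195 in the overexpression strain and 122 in the wild type. Inside it SCN_RS30355 to SCN_RS30870, 57 tags, met the limits for a run in the wild type itself, with 2 counts there, 0 in the overexpression strain and 2435 in the vector control. Of the 195 counts in the overexpression strain, 191 fell on a pair of tags, leaving 4 counts over the other 232 tags, where the wild type had 79 and the vector control 6245.

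**Figure D1:**
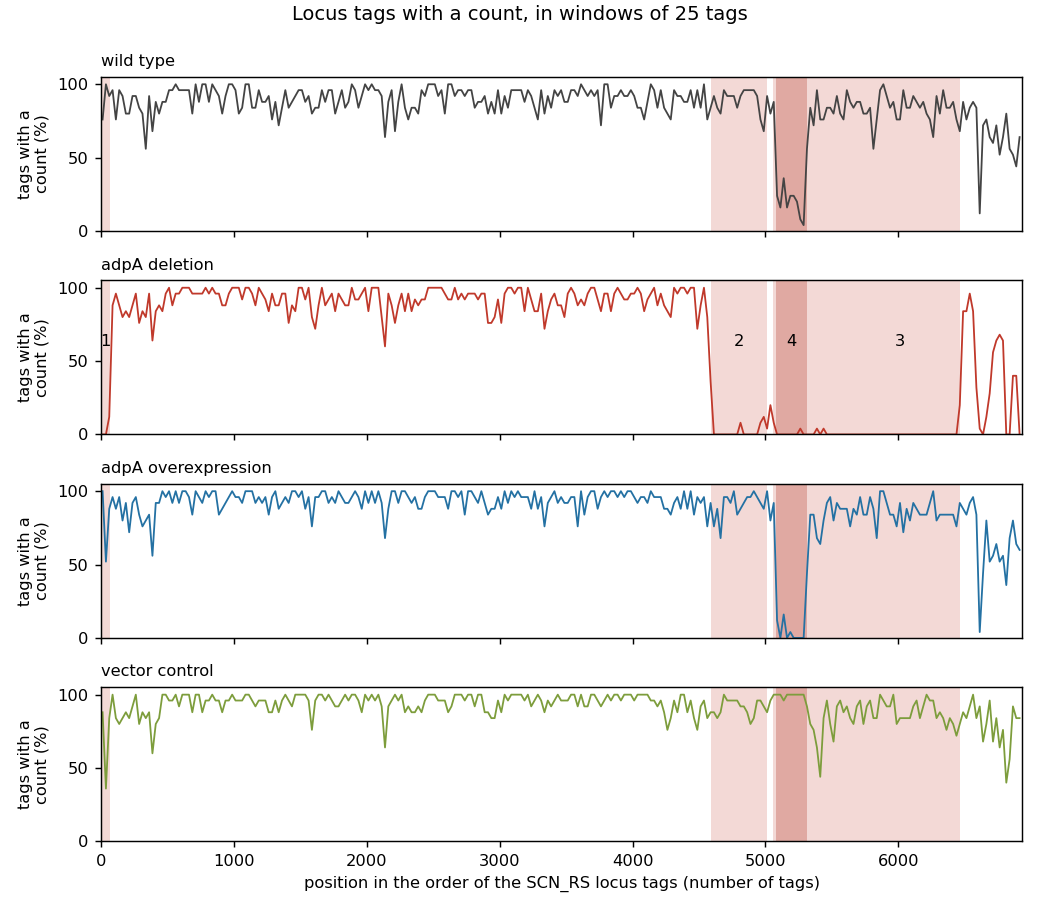
Percentage of locus tags with at least 1 rounded count (y axis) in windows of 25 tags along the order of the SCN_RS tags (x axis), 1 panel per library, with runs 1 to 3 shaded and run 4 shaded darker. The deletion library lies at or near 0 over runs 1 to 3, where the vector control had counts on 88.4% of the tags, and most tags of run 4 had a count in the vector control alone.

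Comparing the deletion with its parent asks which transcripts depend on adpA. Of 4020 genes used, 901 were 2-fold or more higher in the deletion and 1520 were lower, but 677 of the lower genes lay in runs 1 to 3. Outside the runs, 901 genes were higher and 843 lower among 3341. Of the 901, 52 had 0 counts in the wild type, and 83 of the 843 had 0 counts in the deletion. The further blocks and the tags between runs 2 and 3 held 45 of the 843 lower genes and 37 of the 83 at 0, and without them 900 genes were higher and 798 lower among 3295. By log2 ratio with the prior count, the largest increases that also held against the vector control were SCN_RS09320 at 8.21, with 2 counts in the wild type and 1670 in the deletion, 484-fold (interval 134 to 3997), and SCN_RS00545 at 8.13, with 32 and 16068 counts, 291-fold (206 to 425). Against the vector control the log2 ratios of these tags were 3.18 and 5.86. With the floor of 3 counts in the wild type, SCN_RS09320 was 322-fold higher. All 10 of the largest decreases lay in runs 1 to 3, which were defined by tags at 0 in the deletion, and had 0 counts in that library. They were led by SCN_RS26880, with 3351 counts in the wild type and a level at least 1928-fold lower in the deletion, and SCN_RS26875, with 1914 counts and at least 1102-fold lower.

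Adjacent genes often moved together in the deletion, though stretches of this kind were more numerous between vector control and wild type, as given below. Between runs 1 and 2, 183 genes lay in 25 stretches of at least 5 adjacent higher tags, where shuffling the tag order gave 0.947 stretches on average and 5 at most. For lower tags there were 15 stretches with 99 genes, and 0.449 stretches on average in shuffled order. The longest higher stretch was SCN_RS17660 to SCN_RS17760, 20 tags with 440 counts in the wild type and 13972 in the deletion, a log2 ratio of their sums of 4.20 (4.06 to 4.34). That stretch was also high in the overexpression strain and in the vector control, at 21226 and 28055 TMM-scaled CPM against 928 in the wild type, so its median log2 ratio was -0.60 when the deletion was set against the vector control. The stretch SCN_RS17290 to SCN_RS17350, 13 tags, was higher in the deletion against both references, with median log2 ratios of 1.93 against the wild type and 2.53 against the vector control. It was also higher in the overexpression strain, with median log2 ratios of 1.41 to the vector control and 0.78 to the wild type. The longest lower stretch was SCN_RS24905 to SCN_RS24995, 16 tags with 6595 counts in the wild type and 3266 in the deletion, a log2 ratio of -1.80 (-1.86 to -1.74), while the median log2 ratio against the vector control was 2.75.

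The choice of reference changed how many genes were called. Against the vector control, 546 genes were higher in the deletion and 1839 lower, of 4452. Against both references in the same direction, 182 genes were higher and 699 lower. All 182 higher genes and 243 of the 699 lower genes were outside the runs.

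**Figure D2:**
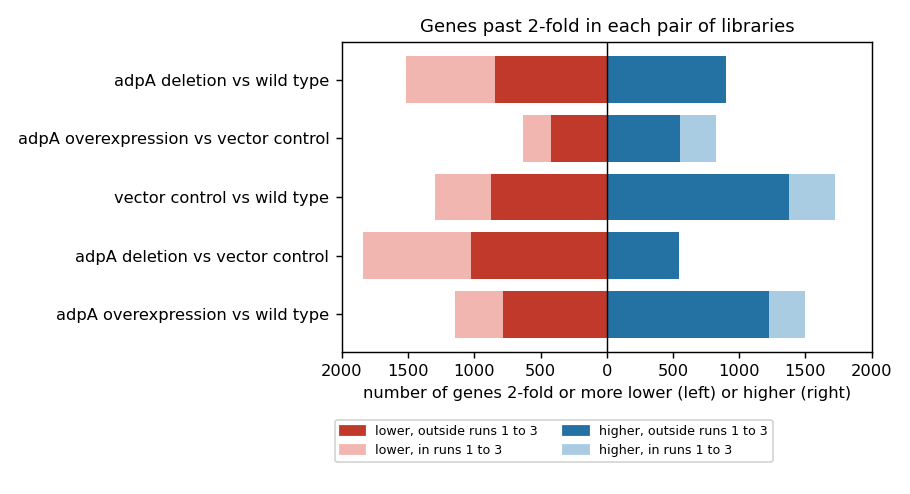
Number of genes 2-fold or more lower (bars to the left of 0) or higher (bars to the right) in each pair of libraries, with the part in runs 1 to 3 in the lighter shade. In the deletion against wild type, 677 of 1520 lower genes and 0 of 901 higher genes lie in the runs.

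Comparing the overexpression strain with the strain carrying the empty plasmid asks what extra adpA changes on the same plasmid background. Of 4583 genes used, 821 were 2-fold or more higher and 632 lower, and outside the runs 556 were higher and 424 lower among 3640. Which direction had more genes depended on the scaling and unit, since library totals gave 740 higher and 747 lower and FPKM gave 766 and 807. Inside run 4, 85 of the 87 genes used were lower, 84 of them with 0 counts in the overexpression strain. Run 4 was defined by tags at 0 in that strain, which largely fixes these decreases and those in run 4 given next. On that log2 scale the largest increases that also held against the wild type were SCN_RS17860, with 109 counts in the vector control and 8336 in the overexpression strain, 96-fold (79.4 to 117), and SCN_RS35320, in run 3, with 2 and 331 counts, 208-fold (57 to 1722). With the floor of 3 counts in the vector control, SCN_RS35320 was 138-fold higher. All 10 of the largest decreases with at least 50 counts in 1 of the libraries lay in run 4. Of the 10 largest that also passed 2-fold lower against the wild type on that log2 scale, 4 lay there. They were led by SCN_RS29810, with 628 counts in the vector control and a level at least 167-fold lower in the overexpression strain, and SCN_RS30330, with 185 counts and at least 49.1-fold lower. Both had 2 counts in the wild type and 0 in the overexpression strain, as had another of the 4. Against the wild type these tags passed only through the prior count, since 2 counts lie under the floor of 3. A decrease against the wild type was therefore not shown for them.

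In this comparison 146 genes lay in 21 stretches of adjacent higher tags between runs 1 and 2, and 49 genes in 6 stretches of lower tags, where shuffled orders gave 0.079 and 0.013 stretches on average. The longest higher stretch, SCN_RS08925 to SCN_RS09000 with 16 tags, had 280 counts in the vector control and 2641 in the overexpression strain, a log2 ratio of 3.57 (3.39 to 3.75). It had 103 counts in the wild type and 53 in the deletion. A further 9 tags, SCN_RS12965 to SCN_RS13010, had 429 counts in the vector control and 3985 in the overexpression strain, a log2 ratio of 3.54 (3.40 to 3.69), with 31 counts in the wild type and 167 in the deletion. The longest lower stretch, SCN_RS20395 to SCN_RS20460 with 14 tags, had 50593 counts in the vector control and 13299 in the overexpression strain, a log2 ratio of -1.60 (-1.63 to -1.57). The wild type and the deletion were lower still, at 8694 and 13042 TMM-scaled CPM against 17673 in the overexpression strain. In the stretch SCN_RS20760 to SCN_RS20805, 9 tags, the overexpression strain had a median log2 ratio of -2.04 to the vector control and -2.32 to the wild type, and the deletion had 1.49 to the wild type. With the wild type as reference, 1495 genes were higher in the overexpression strain and 1147 lower. Against both references 372 genes were higher and 99 lower, of which 261 and 74 were outside the runs.

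**Figure D3:**
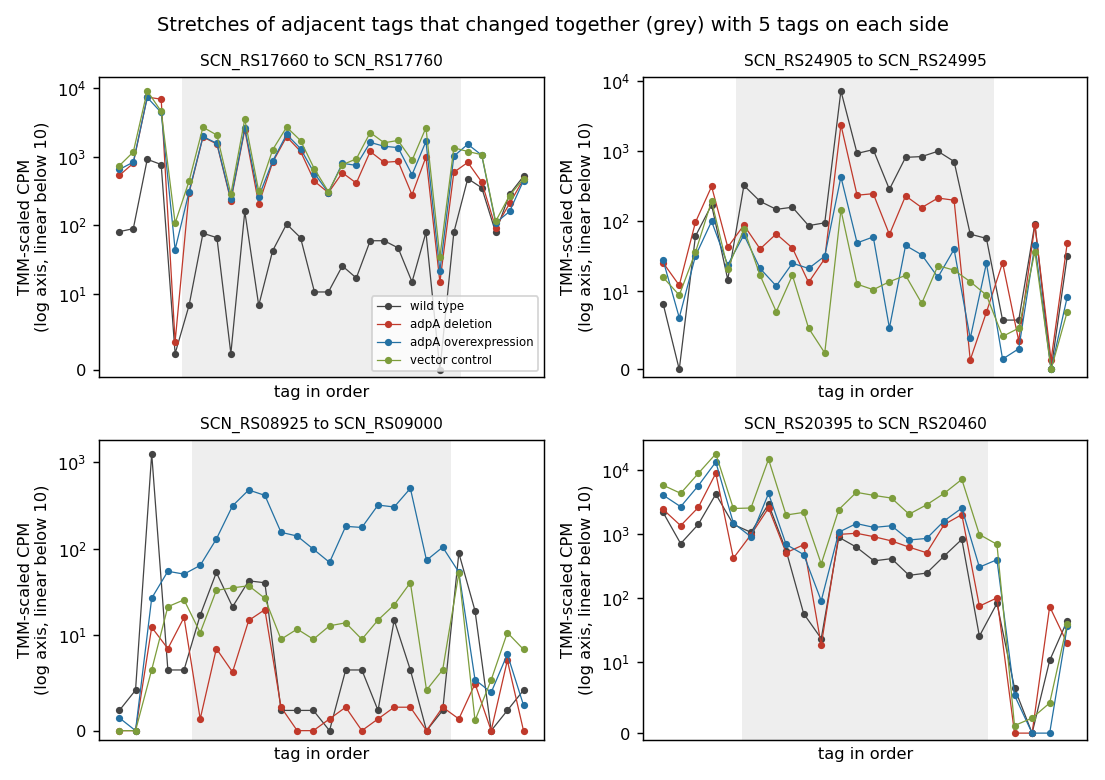
TMM-scaled CPM (y axis, logarithmic above 10) of each tag in 4 stretches of adjacent tags that changed together, shaded grey, with 5 tags on each side in tag order (x axis); lines and points are the 4 libraries. The wild type lies below the other libraries in SCN_RS17660 to SCN_RS17760 and above them in SCN_RS24905 to SCN_RS24995, and the overexpression strain lies above the others over most of SCN_RS08925 to SCN_RS09000.

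Neither the vector control nor the wild type is labelled as changed in adpA, so their difference gives the size of change between single libraries of reference strains. By the number of genes past 2-fold it was larger than either of the other main comparisons. Of 4742 genes used, 1720 were higher in the vector control and 1295 lower, and outside the runs 1372 were higher and 872 lower among 3705. The standard deviation of log2 ratios across genes outside the runs was 2.15, against 1.92 for deletion with wild type and 1.12 for overexpression with vector control. Over all features it was 2.31, under the 2.59 for deletion with wild type. Among 2147 genes outside the runs with at least 50 counts in 1 of the libraries, 1361 passed 2-fold between vector control and wild type. The overexpression strain and the vector control were the closest pair, with 531 of 2093 such genes past 2-fold, 25.4%. The share was 43.9% for deletion with vector control and 44.0% for deletion with overexpression strain. It was highest in the pairs with the wild type, at 55.2% for the deletion, 60.2% for the overexpression strain and 63.4% for the vector control, so the deletion was closer to both plasmid strains than to its parent.

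By log2 ratio with the prior count, the largest increases in the vector control were SCN_RS33305, in run 3, at 9.89, with 1 count in the wild type and 4293 in the vector control, a ratio of 2155 (386 to 85119), and SCN_RS18410, at 8.53, with 1 and 1665 counts, a ratio of 836 (150 to 33025). The largest decreases on the same scale were SCN_RS05550, at -9.30, with 1117 counts in the wild type and 1 in the vector control, a ratio of 2226 (399 to 87987), and SCN_RS00190, in run 1, at -8.82, with 572 and 0 counts, at least 380-fold lower. SCN_RS05550 had 5049 counts in the deletion and 9 in the overexpression strain. With the floor of 3 counts in place of 1, the ratios of SCN_RS33305, SCN_RS18410 and SCN_RS05550 were 718, 279 and 742. The longest higher stretch was SCN_RS17635 to SCN_RS17770, 27 tags, with a log2 ratio of 3.67 (3.60 to 3.74), and the longest lower one was SCN_RS24905 to SCN_RS24995, 16 tags, at -5.12 (-5.27 to -4.97).

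The deletion and the vector control differed from the wild type in much the same direction. Outside the runs, 673 genes were higher in both and 606 lower in both among 3247, where independent lists would share 279 and 226, and 32 and 12 moved in the opposite orientations. Both comparisons use the same wild type library. Simulated unchanged strains against that library shared 26.9 higher and 5.44 lower genes, and part of the excess may come from the shared library. Spearman's correlation of the 2 sets of log2 ratios across genes was 0.78 against 0.64 in the simulation, and their covariance was 3.06 against 0.0932. Genes are not independent replicates, so these values describe the libraries.

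Deletion with wild type and overexpression with vector control share no library, and they were set side by side to ask whether removing and adding adpA moved genes in opposite directions. Of 3603 genes used in both, 386 were lower in the deletion and higher in the overexpression strain, where independent lists would share 197, and 158 were higher in the deletion and lower in the overexpression strain, where 84 would be shared. In the same direction, 67 genes were higher in both against 140 for independent lists, and 102 were lower in both against 119. Outside the runs the 4 counts were 209, 158, 67 and 48, with 91, 83.3, 114 and 66.8 for independent lists. When both strains were set against the vector control, the excess was in the other pairs. Outside the runs, 128 genes were then higher in both and 222 lower in both, with 53.6 and 125 for independent lists, and the opposite pairs numbered 126 and 40, with 127 and 52.6. The vector control library is shared there. Simulated unchanged strains, which hold counting noise only, gave 5.21 and 4.61 genes in the same direction, so an effect of the vector control culture itself was not tested. The log2 ratios correlated across genes at 0.26 against 0.43 in the simulation, with a covariance of 0.359 against 0.0502.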

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

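The alternatives that leave out the runs, thin the libraries or recompute TMM factors were chosen after seeing the data. Of 164 values of the 14 counts of genes under alternatives, 130 were within 1.5 times the main count, among them all under DESeq2 factors, library totals, FPKM, a prior count of 0.5, thinning to the smallest total and TMM without the most abundant feature or the runs. A filter of 50 counts left fewer genes to test. It gave 588 higher and 605 lower for deletion with wild type, 417 and 314 for overexpression with vector control, and 1071 and 614 for vector control with wild type. It also gave 165 genes lower than both references in the deletion and 31 in the overexpression strain, 116 and 90 opposite pairs, and 38 higher and 26 lower in both. Without a filter, which adds genes of under 10 counts, 2447 were lower in the deletion, 1377 lower there than both references and 197 in the overexpression strain, with 580 pairs of deletion lower and overexpression higher and 225 lower in both. A prior count of 10, which shrinks ratios of low counts, gave 377 lower for overexpression, 47 lower than both references, 100 pairs of deletion higher and overexpression lower and 60 lower in both. Outside the runs, where fewer genes are tested, 843 were lower in the deletion, 243 lower than both references, 209 deletion lower and overexpression higher and 48 lower in both. Leaving out the further blocks and the tags between runs 2 and 3 as well gave 798, 209, 202 and 38 for these, with 386 lower for overexpression and 845 lower for vector control with wild type. With the other reference strain 546 were higher in the deletion, and 1495 higher and 1147 lower in the overexpression strain; the cause was not tested. Scaling moved all ratios by up to 0.16 on the log2 scale for the deletion (TMM without the most abundant feature), by -0.14 for overexpression (library totals) and by -0.24 for vector control with wild type (TMM outside the runs). Overexpression had more higher than lower genes, but not with library totals (740 and 747) or FPKM (766 and 807). Of 80 values of named tags 18 left their counting interval, under a prior count of 10 or the other reference, and none changed direction. The alternatives planned for gene lists, adpA and replicons were not run because tags were not paired with names, and a filter does not alter a named tag's ratio. No paired analysis was possible because each group had 1 library. Depth limited tags of few counts, with a floor of 6.33 CPM in the wild type.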

Other observations

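The tests of this part on the runs, on the wild type counts of run 4 except the comparison of profiles, on depth and on an effect of adpA were chosen after the values were seen, and the runs they refer to were also defined then.

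Outside the runs, 1629 locus tags had at least 20 counts in each of the wild type, the overexpression strain and the vector control, and 16 of them had 0 counts in the deletion. Of these 16, 5 were 2-fold or more higher in the overexpression strain than in the vector control, as a gene missing from the deletion strain and also carried on the plasmid of the overexpression strain would be, so the pattern singles out no one tag. Of the 16, 7 lay in the further blocks that were mostly without counts in the deletion and 5 between runs 2 and 3, and 3 of the 5 with the pattern were in those blocks. The pair with the pattern that lay elsewhere, chosen after their values were seen, were SCN_RS09375, of 1200 bp, with 191 counts in the wild type, 1542 in the overexpression strain and 627 in the vector control, and SCN_RS12365, of 396 bp, with 412, 201 and 34 counts. Neither was taken to be adpA, since the tables give no names. The 48 features without a locus tag took 0.629% of counts in the wild type, 0.143% in the deletion, 0.877% in the overexpression strain and 0.593% in the vector control.

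The lack of counts in runs 1 to 3 of the deletion library was weighed against 3 explanations. If entries had been taken out of its table after counting, the total implied by counts, lengths and FPKM would exceed the listed total by at least the 9.46% these runs held in the vector control, but it did so by 1.35%, against 1.67% to 2.98% in the other tables. The candidate explanation that the strain had lost a large plasmid and both chromosome ends was tested by matching pairs of lengths of adjacent tags with pairs in the gene order of the reference ASM551946v1. Of 1893 pairs in the runs only 912 matched and the rest were placed nowhere, and 97.4% of the 912 fell on its plasmid or in the outer 10% of either side of its chromosome, against 11.8% of the 3143 matched of 5033 for other tags; in run 3 without run 4, 598 of 1174 pairs matched, 582 of them on the plasmid, while shuffled orders matched 285 of 6933 pairs on average against 4055. The matching did not tell the sides of the chromosome apart. In the outer 10% lay 356 matched pairs of other tags, against 49 of run 1 and 247 of run 2. Loss of both ends, or of a whole end, was therefore not shown. As a hypothesis the deletion strain, or the culture sampled, may lack DNA of the matched parts of the runs. Genes that were present and silent remain open, since 65 of the 66 well-counted tags at 0 could come from either in RNA from 1 library. How many counts silent genes would leave was not tested.

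The low counts of run 4 in the wild type, 79 over 232 tags or 1.27% (1% to 1.58%) of the vector control's, were weighed against reads carried over from the vector control library. Carry-over would give every gene at least that ratio, but 16 of 343 other genes with at least 500 counts in the vector control lay under it beyond counting error, with 81 wild type counts where 427 were predicted. The wild type culture could instead hold a minority of cells with the run. Its profile over the tags differed from that of the vector control beyond counting error, with a share of 0.0001 of simulated pairs as far apart, the smallest 10000 simulations can give. That bound was wrongly set, because 47 of 100 random sets of other tags, thinned to the same counts, differed as much between these libraries. The question therefore stays open. Of the pairs of lengths in run 4, 12 of 233 matched the reference, 4 of them on its plasmid. That share is near the 285 of 6933 pairs that shuffled orders matched on average, so run 4 was not placed on the reference.

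The excess of genes that moved oppositely in the deletion and the overexpression strain was weighed against unequal depth and against the reference libraries. With all libraries thinned to the smallest total, opposite pairs outside the runs were 2.07 times the number for independent lists. The interval over 1000 resamples of genes was 1.92 to 2.23, and the ratio at full depth was 2.11. This argues against unequal depth. The wild type was the smallest library and kept all its counts, so its own low depth was not tested. Resampling intervals in this paragraph treat genes as independent, though adjacent genes moved together, and cover no difference between cultures. Of the 367 opposite pairs, 323 were genes 2-fold or more apart between vector control and wild type, where independent lists would give 169, a ratio of 1.91 (1.78 to 2.04). Among the 1328 genes closer than that, opposite pairs were 1.64 times (1.26 to 2.09) and pairs in the same direction 1.53 times the number for independent lists. Spearman's correlation of the 2 sets of log2 ratios was -0.018 among them, against -0.443 among the 1746 genes further apart. The opposite tendency was thus seen mainly where the references differed, so a difference between the reference libraries was not excluded. An effect of adpA on these 367 genes cannot be told apart from differences between single cultures without replicate libraries.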
